A study of Mus musculus with 2 samples.

How the data were processed

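Long-read RNA sequencing had been done on total RNA from the left cerebral cortex of mice of strain B6NCrl, aged 6 months, in 2 libraries that the labels give as biological replicates 1 and 2 of 1 group. The labels give both tissue samples the same donor record, describe the tissue as male in 1 field and give the sex as not collected in another. The deposited tables hold counts: whole reads assigned to each transcript model in each library, with no normalization, and every model listed has at least 1 read. Per the file headers, the tables also hold other values, namely the number of exons and the length of each model. The deposited annotations hold, for each library, the positions of the GENCODE M21 features on mm10 together with models added from that library's reads by TALON, a program that classes long reads against an annotation. Per the deposited notes, the counts derive from an alignment made apart from an unfiltered one. The sequencing instrument, the aligner and the version of TALON are not given in the sources used here. Alignments, reads and the genome sequence were not used here. The classes of the models were kept as deposited: known, incomplete match of an annotated intron chain (ISM), annotated splice sites in a new combination (NIC), at least 1 splice site outside the annotation (NNC), antisense, genomic and intergenic.

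Model counts were summed per annotated gene and scaled to CPM (counts scaled to a library total of 1e6), 1306424 in replicate 1 and 1304133 in replicate 2. A single read stood for 0.765 CPM in replicate 1 and 0.767 CPM in replicate 2, and the limit for a count of 0 was set at 3 counts. Values are the mean and SD of the 2 libraries, and shares of reads in a single library have 95% Clopper-Pearson intervals. Genes with at least 10 counts in total were compared between the libraries by an exact two-sided binomial test against the library totals, adjusted by Benjamini and Hochberg's method. A gene was called at an adjusted p under 0.05 and an absolute log2 ratio of at least 1, with 0.5 counts added. With 1 group no model can separate replicate spread from the difference, so edgeR and DESeq2 supplied only normalization factors for alternative settings. Other splits of the samples and a test for outlying samples were not possible with 2 libraries. No paired analysis was possible because there was only 1 group.

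Gene lists were fixed for excitatory and inhibitory neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial cells, mural cells, meningeal fibroblasts, choroid plexus, ependymal cells, red blood cells, striatum, hippocampus, thalamus, olfactory bulb, immediate early genes, synaptic vesicles, glutamate and GABA receptors, calcium and calmodulin signalling, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, chaperones, the mitochondrial genome, sex-linked genes and a splicing panel of 77 genes. The median log2 ratio of each list with enough tested members was ranked among 10000 random lists of the same size, drawn from genes in the same of 20 bins of mean expression, with a two-sided p.

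Isoforms were counted on known transcripts in genes with at least 20 such reads in each library. A major isoform held at least 10% of these reads in both. The share of the leading isoform was compared between the libraries by Fisher's exact test. Exon inclusion was the share of reads on models holding an annotated internal exon with both ends exact, over these plus reads on models with an intron across it, with at least 20 informative reads in each library. Exons without any including read or without any skipping read over both libraries were left out. Chains of introns outside the annotation were matched between libraries by chromosome, strand and every intron position. The gene lists, tests, thresholds, the alternative settings not named otherwise and the rule for named genes were fixed before the data were examined. That rule takes the 10 nuclear genes of highest mean CPM, the 2 to 4 most abundant members of each list, the 10 called genes of largest log2 ratio in each direction, and the sex-linked list. It also takes up to 20 panel genes, in order of informative reads, with at most 2 exons each at 10% to 90% inclusion, the 10 genes of most reads whose leading isoform held under 50% in both libraries, the 5 genes of lowest adjusted p for the leading share, and the 10 most abundant chains outside the annotation found in both libraries. The text does not give every gene that the rule takes.

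GC content was measured on the leading known transcript of a gene, or its longest annotated one, over the whole length and as the highest value in any window of 100 bases. The window was chosen after several sequence measures had been compared with the library ratio, and 99.9% of called genes had a sequence. Near copies of named genes were searched with blastn at 97% identity over at least 200 bases. Alternative settings fixed at the same time changed the normalization (edgeR's TMM factors, DESeq2's size factors), the count minimum, the pseudocount, the classes of reads counted, the size limit, the unit of class shares, the definition of a major isoform, the matching of intron chains, and the replicates used. Alternatives chosen after seeing the data were random lists matched also on peak GC content, all same-strand reads on models with at least 50% of their bases over the gene's own exons, and genes up to the median peak GC content alone. A gene's own exons were here those of every model given to it in either library, unspliced models included. The GC-matched lists used fewer and wider bins of mean expression than the 20 of the main test, each split into bins of peak GC content.

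The tests were tested on simulated data. Of 100 genes with a simulated 2-fold change, 73.0% passed the adjusted p and 48.0% also the size limit, which lies at the simulated change itself, and of 100 with a 4-fold change 94.0% passed both. The changed genes were drawn from genes with at least 50 counts, which 6612 of the 11838 tested genes had. Changes in rarer genes were not simulated. Of 11615 unchanged genes 7 were past the adjusted p, and 2 of 40 lists without change had a p under 0.05. The simulated libraries differed by counting noise alone, and the lists held genes drawn at random. The real libraries differed by more than counting noise, with a chi-square of 7.08 per degree of freedom. The rates of false calls for such a spread, or for lists of genes that vary together, were not simulated. Among 100 genes with a simulated change of the leading isoform 99.0% were found, beside 6 of 900 without one. These rates hold only for the size of change and the read numbers that were simulated. They do not give the share found among smaller changes or in genes with fewer reads. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 and blastn 2.17.0+.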

Results

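The data described gene and transcript abundance in the left cerebral cortex of adult mice of strain B6NCrl, aged 6 months, by long-read RNA sequencing, in which a single read can span a transcript from end to end. The labels gave 1 group of 2 biological replicates, so no conditions were compared. Each replicate was a library of its own tissue sample, and both tissue samples carried the same donor record. The labels did not state whether they came from separate animals, and the spread between replicates may therefore be technical in part. Replicate 1 held 1306424 reads and replicate 2 held 1304133 reads. A count of 0 allowed up to 3 counts, or 2.30 CPM (counts scaled to a library total of 1e6), in either library. Intervals and limits below cover counting error only. Positions refer to mouse genome build mm10 with GENCODE M21 gene models.

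The most abundant nuclear genes of the cortex ranged from those of a protease inhibitor and ferritin to those of a chaperone, beta actin and calmodulin. Cst3 (ENSMUSG00000027447.6, chromosome 2, 148871722 to 148875692), which encodes the secreted protease inhibitor cystatin C, led the nuclear genes with 7182 ± 1705 CPM (SD, n = 2). The calmodulin gene Calm2 had 3471 ± 693 CPM. Fth1, the ferritin heavy chain, had 6978 ± 268 CPM, and the lipid carrier gene Apoe had 6819 ± 1156 CPM. The brain creatine kinase gene Ckb had 6295 ± 777 CPM, the chaperone gene Hspa8 had 4728 ± 67.1 CPM, Ptgds, a prostaglandin D synthase, had 4519 ± 841 CPM, and Actb, the cytoplasmic beta actin, had 4208 ± 1313 CPM. Gm10925, at 4064 ± 29.4 CPM, was 100% identical over 678 bases to the mitochondrial gene mt-Atp6, so its reads could not be assigned to the nuclear genome. The highest value of any gene was that of mt-Rnr2, the large mitochondrial ribosomal RNA, at 27365 ± 11016 CPM. Of the 55536 annotated genes, 17049 had a read in replicate 1 and 17007 in replicate 2, and 15149 had a read in both. Annotated transcripts with a read numbered 20646 in replicate 1 and 19532 in replicate 2, and 15546 were seen in both. Annotated genes took 94.9% of reads in replicate 1 and 93.3% in replicate 2.

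Markers of the main cell types of cortex were detected in both libraries. Astrocyte markers were the most abundant cell type list, at 17640 ± 2674 CPM in sum (SD, n = 2). Most of this sum came from Cst3, Apoe and the glycolytic gene Aldoc (1722 ± 16.8 CPM). Which cells the reads of these genes came from was not tested, so the sums do not rank the cell types themselves. Oligodendrocyte markers summed to 6101 ± 205 CPM, with the myelin gene Mbp at 2867 ± 461 CPM and the transferrin gene Trf at 854 ± 91.0 CPM. Inhibitory neuron markers summed to 1729 ± 148 CPM, with the neuropeptide genes Cck at 981 ± 37.5 CPM and Npy at 264 ± 39.9 CPM, and Gad1, which makes GABA, at 174 ± 0.216 CPM. Excitatory neuron markers summed to 1193 ± 148 CPM, with Camk2a at 414 ± 164 CPM and Nrgn at 343 ± 271 CPM. Endothelial cell markers summed to 1478 ± 98.9 CPM, most of it from Bsg (1103 ± 103 CPM), and the tight-junction gene Cldn5 had 164 ± 20.2 CPM. Microglia markers summed to 1147 ± 55.1 CPM, with the complement genes C1qa at 184 ± 15.4 CPM and C1qb at 147 ± 6.32 CPM. Oligodendrocyte precursor markers had 345 ± 111 CPM, with Bcan at 172 ± 26.9 CPM and Olig1 at 93.1 ± 29.7 CPM. Mural cell markers had 135 ± 3.42 CPM, with Vtn at 66.3 ± 8.04 CPM and Rgs5 at 27.6 ± 10.9 CPM.

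Cell types and regions next to the cortex left weaker signals, apart from the striatum list. Meningeal fibroblast markers summed to 125 ± 36.1 CPM (SD, n = 2), led by Mgp (49.8 ± 19.4 CPM) and Slc6a13 (29.1 ± 8.63 CPM). Choroid plexus markers had 50.2 ± 14.6 CPM, of which Ttr gave 45.6 ± 14.6 CPM and Clic6 1.53 ± 1.09 CPM. Red blood cell markers had 28.0 ± 14.6 CPM, led by the globin genes Hbb-bs (10.7 ± 9.74 CPM) and Hba-a1 (8.81 ± 4.86 CPM), each of which has a near copy in the genome. Ependymal markers had 25.3 ± 4.37 CPM, led by Rarres2 (13.8 ± 6.52 CPM) and Tmem212 (4.98 ± 0.536 CPM). Striatum markers reached 680 ± 4.03 CPM, led by Penk (278 ± 37.7 CPM), which encodes proenkephalin, and Ppp1r1b (218 ± 31.2 CPM), both of which some cortical cells express as well. Thalamus markers had 27.2 ± 2.74 CPM, with Slc17a6 at 14.6 ± 2.18 CPM and Tcf7l2 at 5.75 ± 1.63 CPM. Hippocampus markers had 9.96 ± 2.18 CPM, with Fibcd1 at 4.98 ± 2.71 CPM and Prox1 at 3.83 ± 1.09 CPM. Olfactory bulb markers had 9.19 ± 1.09 CPM, with Doc2g at 4.21 ± 2.70 CPM and Th at 3.07 ± 1.09 CPM.

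Genes of energy supply, translation and synaptic function held a large part of the reads. The mitochondrial genome gave 47347 ± 9717 CPM (SD, n = 2), with mt-Nd1 at 4458 ± 455 CPM after mt-Rnr2. Nuclear genes of oxidative phosphorylation gave 16786 ± 237 CPM, led by Cox8a (3121 ± 222 CPM) and Cox4i1 (2989 ± 165 CPM). Genes of glycolysis gave 14188 ± 7.32 CPM, led by Aldoa (2973 ± 245 CPM), Aldoc and Ldhb (1712 ± 70.4 CPM). Cytosolic ribosomal protein genes gave 16294 ± 689 CPM, led by Rpl3 (1838 ± 282 CPM) and Rpl13 (1407 ± 22.1 CPM). Calcium and calmodulin signalling genes gave 16290 ± 752 CPM, with Ppp3ca, a catalytic subunit of calcineurin, at 1046 ± 74.5 CPM beside Calm2. Heat shock and chaperone genes gave 9197 ± 228 CPM, with Hsp90ab1 at 2529 ± 66.0 CPM after Hspa8. Synaptic vesicle genes gave 7662 ± 1936 CPM, led by Snap25 (3051 ± 158 CPM), which drives vesicle fusion, Rab3a (775 ± 265 CPM) and Syt1 (753 ± 56.2 CPM). Glutamate receptor genes gave 951 ± 44.5 CPM, led by Gria2 (335 ± 44.8 CPM) and Grin2b (129 ± 25.3 CPM), and GABA receptor genes gave 875 ± 90.5 CPM, with Gabrd at 134 ± 18.8 CPM and Gabbr1 at 111 ± 36.7 CPM. Immediate early genes, which neurons switch on with activity, gave 790 ± 420 CPM, led by Junb (345 ± 226 CPM), Dusp1 (96.9 ± 55.7 CPM) and Egr1 (93.1 ± 6.93 CPM). The 77 genes of the splicing panel gave 28062 ± 1334 CPM.

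**Figure D1:**
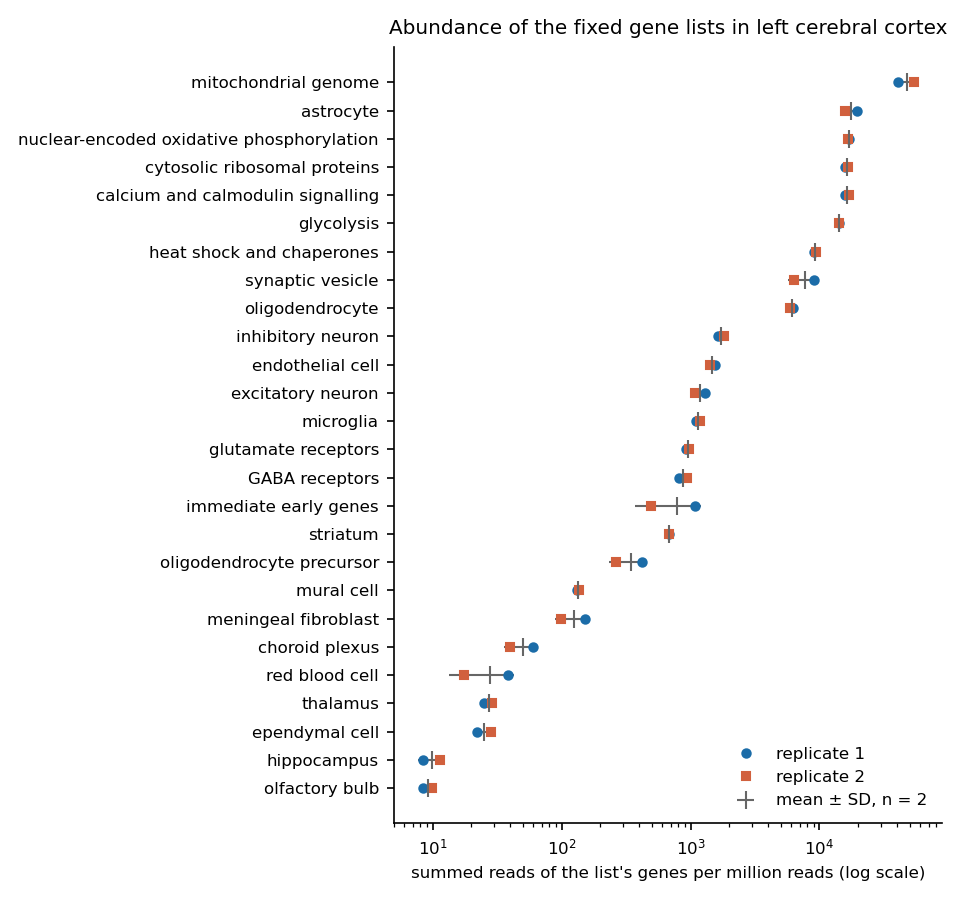
Summed reads of each fixed gene list in CPM, on a log axis, with the 2 replicates as points and their mean and SD. The mitochondrial genome (47347 CPM) and astrocyte markers (17640 CPM) lie far above the markers of hippocampus (9.96 CPM) and olfactory bulb (9.19 CPM).

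The labels describe the tissue as male in 1 field and give the sex as not collected in another. The 4 Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, which are expressed widely in male tissues, had 0 reads in both replicates. Their 4 X-linked counterparts had 153 reads in replicate 1 and 216 in replicate 2, among them Ddx3x with 53 and 88 reads and Eif2s3x with 72 and 87 reads. A count of 0 therefore allowed Y-linked transcripts up to 1.96% of the X-linked ones in replicate 1 and 1.39% in replicate 2. Xist, the RNA made from the inactive X chromosome, had 29 reads in replicate 1 and 27 in replicate 2, or 21.5 ± 1.06 CPM (SD, n = 2). All Xist reads were unspliced, and 23 in replicate 1 and 24 in replicate 2 lay at chromosome X, 103482406 to 103483254.

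The 2 libraries were compared to see how far replicate samples of this cortex resembled each other. Synaptic vesicle genes and immediate early genes were lower in replicate 2 as groups. Of 15 synaptic vesicle genes tested, 6 were lower in replicate 2 and 0 were higher, among them Syp (log2 ratio of replicate 2 to replicate 1, -1.96), Vamp2 (-1.88) and Cplx2 (-1.82), while the most abundant member, Snap25, stood at -0.11. Of 11 immediate early genes tested, 5 were lower and 0 higher: Nr4a1 (-2.59), Arc (-2.01), Junb (-1.45), Ier2 (-1.33) and Dusp1 (-1.24), while Egr1 stood at -0.15. Of 12 calcium signalling genes, 3 were lower, namely Hpca (-1.83), Nrgn (-1.82) and Camk2n1 (-1.02). Of the mitochondrial genome's 15 genes, mt-Nd3 was higher (1.59) and mt-Co1 lower (-1.72), and the share of all reads from this genome was 4.16% in replicate 1 and 5.75% in replicate 2. Lower members of other lists included Slc17a7 (-1.84) beside Nrgn among excitatory neuron markers, Olig2 (-3.81) and C1ql1 (-2.62) among oligodendrocyte precursor markers, Hbb-bs (-2.09) among red blood cell markers and Hk1 (-1.80) in glycolysis. Adora2a (1.18), a striatum marker, was higher. Of the 77 genes of the splicing panel, 3 were lower, namely the G protein gene Gnas (-1.79) beside Syn2 (-1.30) and Syn1 (-1.19). Members outside the most abundant of each list were named after their values were seen. Adjusted over the list alone, the counts were the same for every list but the endothelial one, where 1 gene, Ly6a, was lower against 0 over all genes tested.

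Among 23 lists set against 10000 random lists of matched expression, 4 differed between the libraries. The median log2 ratio was -0.73 for synaptic vesicle genes (adjusted p = 0.00460, from the smallest p the draws can give, 0.0002), -0.84 for immediate early genes (adjusted p = 0.00920), -0.27 for calcium signalling (adjusted p = 0.0287) and 0.34 for the mitochondrial genome (adjusted p = 0.00690). In the last of these, mt-Co1 (-1.72), mt-Cytb (-0.28), mt-Nd1 (-0.21), mt-Nd4l (-0.087) and mt-Atp6 (-0.030) had log2 ratios below 0. Excitatory neuron markers came next, with a median of -0.38 (adjusted p = 0.0994), but their most abundant member, Camk2a (0.83), and Rorb (0.86) had log2 ratios above 0 that passed the adjusted p and not the size limit. Random lists were also matched on peak GC content, a choice made after seeing the data. The GC-matched random lists had fewer and wider bins of mean expression, so both kinds of matching changed. Synaptic vesicle and immediate early genes then each had an adjusted p of 0.00230, while calcium signalling (0.101) and the mitochondrial genome (0.128) no longer passed.

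Across single genes, 644 were lower and 191 higher in replicate 2 out of 11838 tested, by at least 2-fold at an adjusted p under 0.05 (exact binomial test, two-sided). Cebpb (ENSMUSG00000056501.3, chromosome 2, 167688915 to 167690418), a transcription factor gene of a single exon, had 101 reads in replicate 1 and 0 in replicate 2, at least 33.6-fold lower. Dapk3 (ENSMUSG00000034974.13, chromosome 10, 81183005 to 81193197), a kinase gene, had 196 and 2 reads, a ratio of 97.8 with a 95% interval of 26.7 to 813. Mocs3 was at least 13-fold lower (39 and 0 reads) and Gpr162 at least 9.65-fold lower (29 and 0 reads). The chemokine gene Ccl21b was at least 28.0-fold lower (84 and 0 reads), but Gm13304, Gm21541 and Gm10591 hold its transcript with 100% identity, so its reads could not be tied to 1 copy. Gm10801 (33 and 0 reads), the non-coding Gm26870 (27 and 0 reads) and the pseudogene Mpc1-ps (135 and 2 reads, ratio 67.4, interval 18.3 to 562) were also lower, but Mpc1-ps is 99.7% identical over its 330 bases to Mpc1 (435 and 514 reads), so its reads could not be tied to the pseudogene. The transcript of Gm26870 matched itself with 81.5% identity at a shift of 234 bases, as a tandem repeat does, so its reads could not be tied to 1 repeat unit. Among genes higher in replicate 2, Vsig2 had 3 and 149 reads, a ratio of 49.8 with an interval of 16.7 to 244, and St8sia3os had 0 and 12, at least 4.01-fold higher. The difference of Vsig2 was smaller when all same-strand reads over its own exons were counted, with 42 and 149 reads and a log2 ratio of 1.82.

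For 9 other named genes the difference fell below 2-fold with another way of counting reads. In it, a gene's own exons were those of all models given to it in either library, unspliced ones included. They may reach over introns or a neighbouring gene, whose reads then count as well. BC065397 had 1153 and 1518 reads in this count. Counting all same-strand reads over a gene's own exons, whichever gene they were given to, a choice made after seeing the data, BC065397 (106 and 1 reads) had a log2 ratio of 0.40 and Gm38642 (80 and 1) of -0.74. In the same count Rpl21-ps9 (0 and 346 reads) had a log2 ratio of 0.25, Gm48623 (4 and 634) of -0.28, 4921522P10Rik (0 and 65) of 0.53, AC129217.1 (0 and 27) of -0.049, Gm42936 (0 and 15) of 0.60, Nat8f5 (0 and 13) of 0.67 and Gm49356 (0 and 12) of 0.95.

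Genes lower in replicate 2 held GC-rich sequence. The richest 100 bases of the transcript had a median GC content of 83.0% in genes lower in replicate 2, 69.0% in genes higher and 73.0% in the remaining tested genes. Cebpb reached 89.0%, Olig2 87.0% and Syn2 85.0%, while Snap25 reached 65.0%. Arc (74.0%), Nr4a1 (72.0%) and Hpca (72.0%) were lower in replicate 2 without such a stretch. Across 11832 genes, the log2 ratio had a Spearman rho of -0.25 with this peak GC content and -0.27 with the GC content of the whole transcript, and genes are not independent replicates. Tested alone, a choice made after seeing the data, genes in the lower part of peak GC content, up to the median, gave 78 lower and 101 higher genes.

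**Figure D2:**
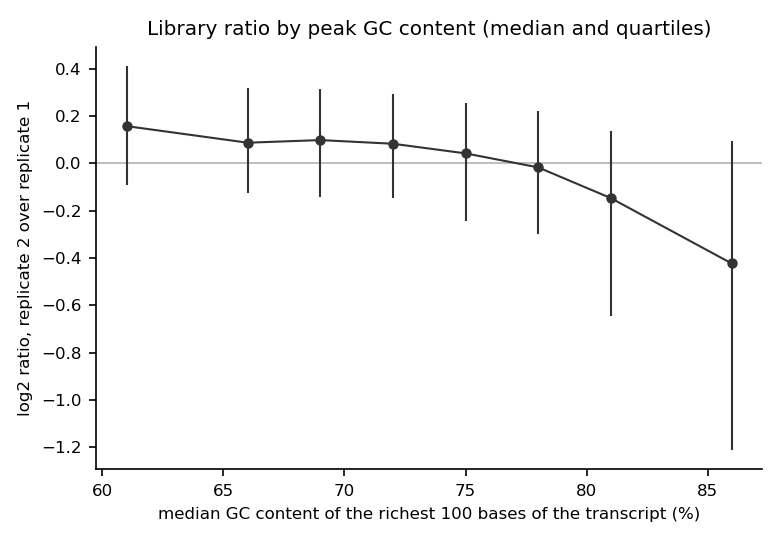
Log2 ratio of replicate 2 to replicate 1 (median and quartiles of genes) in 8 bins of the GC content of the richest 100 bases of the transcript, over 6610 genes with at least 50 counts. The median was 0.16 in the bin of lowest GC content and -0.42 in the bin of highest GC content.

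Between the libraries, gene counts had a Pearson r of 0.915 and a Spearman rho of 0.905 across 11838 genes (log2 CPM with 1 added), where genes are not replicates. Among 6612 genes with at least 50 counts, 78.1% lay within 1.5-fold and the SD of the log2 ratio was 0.71. The chi-square of the 2 count columns was 83802.5 on 11837 degrees of freedom, or 7.08 per degree of freedom. The binomial and Fisher's exact tests here compare 2 libraries against counting noise, and they test no condition. At an adjusted p under 0.05 without a size limit 1519 genes differed, and 2699 had an unadjusted p under 0.05.

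Most reads matched annotated transcripts. Known transcripts took 65.7% ± 3.59 of reads (SD, n = 2), 68.2% in replicate 1 (95% Clopper-Pearson interval 68.1 to 68.3) and 63.1% in replicate 2 (63.0 to 63.2). Models that matched part of an annotated intron chain took 13.9% ± 1.27, and most often they lacked the 5' end of the transcript, with 81912 reads of 169766 in replicate 1 and 94077 of 192858 in replicate 2. Genomic models, largely unspliced reads inside genes, took 8.90% ± 1.69, and antisense models 5.29% ± 1.19. Models with a new combination of annotated splice sites took 2.97% ± 0.347, models with a splice site outside the annotation 2.74% ± 0.136, and intergenic models 0.546% ± 0.0785. Spliced reads were 76.5% of reads in replicate 1 and 70.2% in replicate 2. Known transcripts made up 15.1% of the models. A single read lay behind 79676 of 132801 models in replicate 1 and 77782 of 133303 in replicate 2.

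Long reads showed several transcripts of the same gene side by side. Gpm6b, a neuronal and glial membrane glycoprotein gene, gave 44.2% ± 6.72 of its known-transcript reads to Gpm6b-209 and 21.4% ± 1.11 to Gpm6b-203 (SD, n = 2). Ociad1 gave 46.1% ± 0.568 to Ociad1-201 and 41.3% ± 1.34 to Ociad1-202. Pacsin1, which acts in endocytosis, gave 40.02% ± 1.92 to Pacsin1-211 and 21.7% ± 1.68 to Pacsin1-201. Mef2c, a neuronal transcription factor gene, spread over Mef2c-213 (36.2% ± 7.98), Mef2c-222 (31.7% ± 0.756) and Mef2c-223 (29.3% ± 5.91). The leading isoform held 46.2% ± 4.69 of Tcf25, 42.8% ± 0.783 of Ccl27a, 34.1% ± 3.42 of Serbp1, 48.9% ± 0.856 of Cuedc2 and 43.2% ± 0.749 of the tropomyosin gene Tpm1. Ccl27a has near copies in Ccl27b and Gm13306, so part of its reads may belong to them. Of 3956 genes with at least 20 known-transcript reads in each library, 872 (22.0%) had at least 2 isoforms with 10% or more of the reads in both libraries, and 106 had at least 3. The number was 464 with at least 50 reads in each library and 495 with a limit of 20% of the reads.

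The leading isoform was the same in both libraries for 2466 of 2572 genes (95.9%), with a median share of 92.6%. Its share differed in 45 genes, higher in replicate 2 in 15 and lower in 30 (Fisher's exact test, two-sided, adjusted p under 0.05), and 185 had an unadjusted p under 0.05. Cspg5-202, of the brain proteoglycan gene Cspg5, held 74.2% of the gene's known-transcript reads in replicate 1 (95% interval 69.5 to 78.6) and 7.07% in replicate 2 (2.89 to 14.0; Fisher's exact test, adjusted p = 1.85e-32). Prkcb-202, of a protein kinase C gene, held 72.3% (68.3 to 76.1) and 21.6% (15.3 to 29.1; Fisher's exact test, adjusted p = 1.36e-25). Rnf208-203 held 75.2% (67.6 to 81.7) and 3.64% (0.443 to 12.5). Cox4i1-201 went the other way with 73.4% (72.0 to 74.8) and 83.7% (82.5 to 84.9), and so did Rtn1-201 with 90.4% (89.0 to 91.8) and 98.3% (97.5 to 98.9). The isoforms Cspg5-202, Prkcb-202 and Rnf208-203 had a peak GC content of 85.0%, 80.0% and 80.0%. The isoforms paired with them in the same genes had 71.0%, 59.0% and 69.0%. Cox4i1-201 was also the GC-richer of its pair, with 74.0% against 65.0%. With reads of all classes of the gene in the total, 360 genes differed and the difference of Rtn1-201 was -2.81 percentage points. Among genes whose isoforms differ in length by under 500 bases, 7 differed, but fewer genes were tested. These counts therefore do not measure an effect of read class or of length.

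In a panel of genes with alternative exons in neurons or glia, 64 of 299 exons tested had an inclusion of 10% to 90%, in 32 genes. Only exons with both an including and a skipping read were tested, so this is no share of all exons in the panel. In Pkm, pyruvate kinase, the exon at chromosome 9, 59675029 to 59675195, was in 87.3% ± 1.67 of informative reads and its alternative at 59675568 to 59675734 in 12.3% ± 1.98 (SD, n = 2). In Mbp, the myelin basic protein gene, the 78-base exon (chromosome 18, 82561778 to 82561855) was in 10.4% ± 0.206 and the 123-base exon (82578936 to 82579058) in 17.01% ± 0.860. The mutually exclusive 115-base exons of the glutamate receptor gene Gria2, known as flip and flop, were used about equally, at 49.0% ± 3.90 (chromosome 3, 80690404 to 80690518) and 49.4% ± 5.51 (80691320 to 80691434). The clathrin light chain genes carried their extra exons in most reads, with 75.3% ± 1.31 for the 54-base and 71.2% ± 0.845 for the 36-base exon of Clta and 76.4% ± 1.41 for that of Cltb. In Mapt, which encodes tau, the upstream 87-base exon (chromosome 11, 104287123 to 104287209) was in 19.6% ± 1.05 of reads and the downstream 87-base exon in 10.99% ± 0.95. The 30-base exon of Ppp3ca was in 84.6% ± 3.10. The kinase genes Camk2g (69-base exon 33.9% ± 2.25, 33-base exon 80.4% ± 1.79) and Camk2b (45-base exon 85.4% ± 1.48) and the adhesion gene Cadm1 (84-base exon 37.5% ± 3.74, 33-base exon 44.7% ± 3.36) also used both forms. Tpm3 carried its alternative 76-base exons in 19.4% ± 2.29 and 79.6% ± 2.51, Aplp2 its 36-base exon in 86.1% ± 1.86 and its 168-base exon in 76.9% ± 2.63, and the myelin gene Mag its 45-base exon in 67.2% ± 2.92. Inclusion was 12.2% ± 2.35 for the 57-base exon of Rtn3, 10.8% ± 3.94 for the 172-base exon of Atp2b2, and 55.4% ± 7.99 for the 72-base exon of Bin1.

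**Figure D3:**
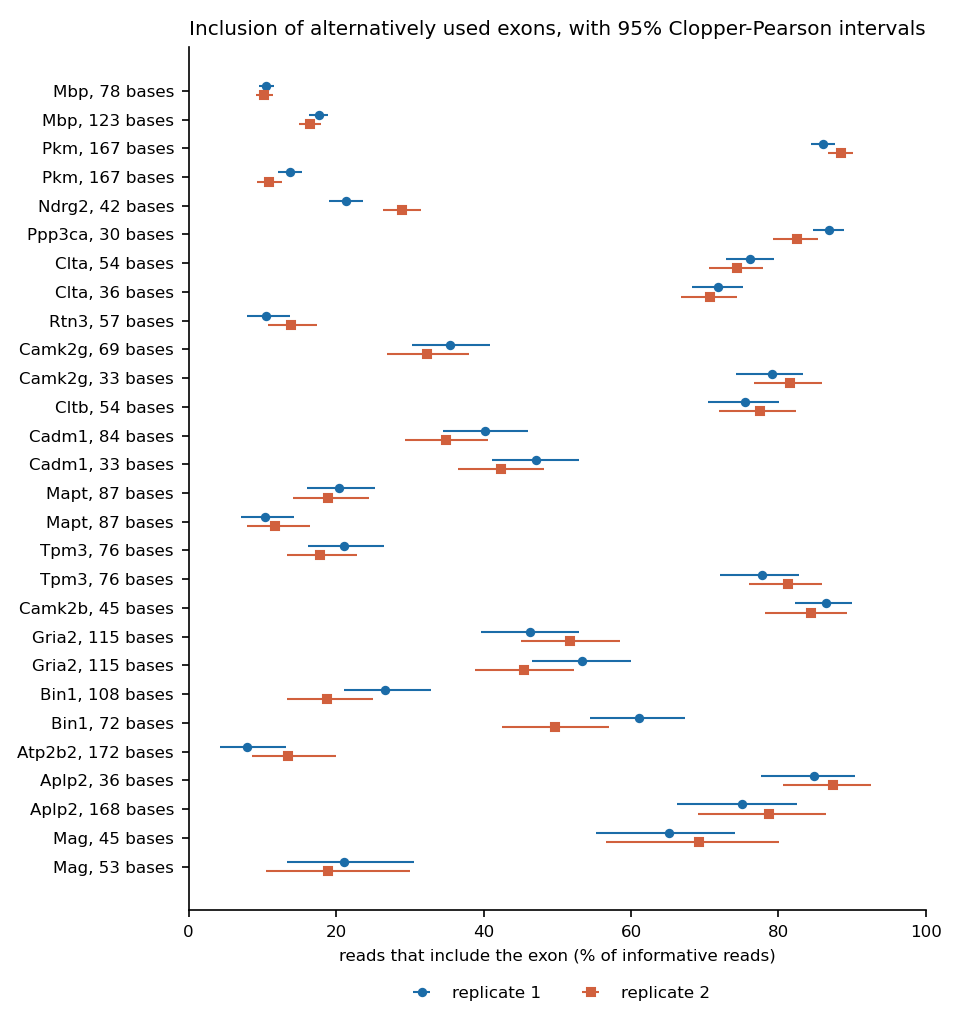
Percent of informative reads that include each alternatively used exon, at most 2 for each gene shown, in replicate 1 and replicate 2 (points), with 95% Clopper-Pearson intervals. Mean inclusion runs from 10.4% in the 78-base exon of Mbp to 87.3% in the 167-base upstream exon of Pkm, and the 42-base exon of Ndrg2 stands at 21.3% and 28.9%.

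Exon use differed between the libraries at 5 exons of the panel, with 26 at an unadjusted p under 0.05 (Fisher's exact test, two-sided). The 42-base exon of Ndrg2, an astrocyte gene, was in 21.3% of reads in replicate 1 (95% interval 19.1 to 23.7) and 28.9% in replicate 2 (26.3 to 31.6; Fisher's exact test, adjusted p = 0.00532). The mutually exclusive 118-base exons of Snap25 stood at 9.47% and 6.63% (chromosome 2, 136769743 to 136769860) and at 90.3% and 93.1% (136770057 to 136770174). In Bin1, which shapes membranes, the 129-base exon stood at 49.8% and 31.4% and the 108-base exon at chromosome 18, 32429196 to 32429303, at 48.4% and 30.6%. The differing exons of Snap25 and Bin1 were named after their values were seen. Among the 64 exons the median difference was 4.26 percentage points, 63 lay in coding sequence and 45 had a length that is a multiple of 3. With known transcripts alone 27 exons lay in this range, and with at least 50 informative reads in each library 42 did.

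Intron chains outside the annotation were found again in the other library for some of the most abundant genes. The chain of Oaz1 (chromosome 10, 80826656 to 80829284), whose protein is made by a shift of the reading frame, held 94.5% ± 0.0314 of the gene's reads (SD, n = 2), and that of its relative Oaz2 held 83.0% ± 0.253. Neither model had an unannotated intron: annotated transcripts of both genes carry gaps of 1 and 4 bases that lie inside an exon of the model. The chain of Uchl1, a neuronal ubiquitin hydrolase gene, held 85.1% ± 1.74, that of Penk 88.4% ± 2.54, that of the pyruvate carrier gene Mpc1 90.8% ± 0.701, that of Vdac3 76.7% ± 2.45, that of Dctn2 71.9% ± 4.50, that of the calcium pump gene Atp2b1 46.3% ± 0.238 and that of Rab3a 28.2% ± 5.48. An intron end lay 1 base from the nearest annotated intron in Vdac3, Penk and Rab3a, 8 bases in Mpc1, 10 in Dctn2 and 116 in Uchl1, and Atp2b1 had only annotated introns. In Mpc1 this intron end was also the end of an annotated gap of 4 bases. The 2 ends of the unannotated Nrgn intron lay 17 and 248 bases from those of the nearest annotated intron. The chain of Nrgn held 81.2% in replicate 1 and 31.0% in replicate 2, with 567 and 61 reads. Of 36135 such chains in replicate 1 and 33934 in replicate 2, 9436 were in both, and they held 58.9% and 59.8% of the reads on such chains. The number in both was 3698 with at least 2 reads in each library and 1144 with at least 5.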

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

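All tests in this part were chosen after the results were seen. Replicate 1 held 85 intergenic models of a single read on the Y chromosome, a signal in data that no comparison of the report uses and above the 3 counts that a count of 0 allows. Replicate 2, at nearly the same depth, held 1. They made up 2.25% of 3784 such models in replicate 1 and 0.0469% of 2132 in replicate 2, and all models on the Y chromosome together held 111 and 10 reads. Replicate 1 had 0.936 such single-read models per Mb on the Y chromosome, 1.01 on the X chromosome and 1.42 on the autosomes. In replicate 2 these values were 0.0110, 0.509 and 0.829.

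The sex-linked reads go against the description of the tissue as male. A male animal whose Y-linked transcripts were missed for lack of depth would leave no Xist, but the lower of the Xist counts was 27 reads, and Ddx3y, Eif2s3y, Uty and Kdm5d had 0. Tissue from female animals may be the source, since it needs Xist reads (56 over both libraries) without reads on these 4 genes, and a wrong label remains open with it. Repeats shared with other chromosomes and placed on the Y chromosome alike in both libraries are argued against by the unequal share of Y models (Fisher's exact test between the 2 libraries, p = 9.75e-16), while repeats read more often in replicate 1 stay open. Traces of male genomic DNA in replicate 1 could give models along the whole chromosome, and 4.71% of them (95% interval 1.3 to 11.6) lay in its first 4 Mb, which hold 4.40% of its length, but repeats could be spread the same way.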

How the results depend on the processing

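Of 49 alternative values of 10 main results, 31 stayed within their limits and 18 moved, and unless a reason is given the cause was not tested. The Pearson r between libraries was 0.939 without a filter, 0.888 with at least 50 counts, 0.853 on known transcripts and 0.908 with a pseudocount of 0.5. Differing genes numbered 863 with TMM factors and 800 with DESeq2's, 1519 without a size limit, by construction, and 179 among genes of lower peak GC content, where fewer genes were tested (chosen after seeing the data, as were the GC-matched lists and the same-strand count). The astrocyte list had 24265 CPM on known transcripts, a smaller total. Lists that differed fell to 2 with GC-matched random lists, which were matched less closely on mean expression. Known transcripts were 15.1% of models and 69.4% of reads on models with at least 2 reads. Genes with several major isoforms numbered 464 with at least 50 reads and 495 at a 20% share. Differing leading isoforms numbered 360 over all classes, where further genes were eligible, and 7 with length differences under 500 bases, where fewer were. Panel exons numbered 42 with at least 50 reads and 27 on known transcripts, and shared chains 3698 with at least 2 reads and 1144 with at least 5, where fewer were eligible. Reversed values were BC065397 at 0.40, Gm48623 at -0.28 and AC129217.1 at -0.049 by same-strand reads, and Rtn1-201 at -2.81 points over all classes. With either replicate left out, detected genes ranged from 17007 to 17049, the astrocyte list from 15749 to 19531 CPM, known transcripts from 63.1% to 68.2%, genes with several major isoforms from 1115 to 1218, and panel exons stayed at 65. Named genes kept direction and call in 146 of 155 alternative values, 6 lost the call and 3 reversed. List tests kept their side in 86 of 89, with 2 weaker and 1 stronger, the splicing panel on known transcripts (median -0.14). Exon inclusion stayed within the spread of the replicates in 163 of 180 values and list sums in 76 of 108. Leaving out a replicate could not move an exon inclusion, a list sum or the share of known transcripts, because this limit is wider than that change. All 32 list sums that moved therefore came from the other settings. Leading isoforms kept direction and call in 11 of 12. Depth limits the tests: among genes with at least 50 counts, 73.0% of simulated 2-fold changes passed the adjusted p, against 94.0% of 4-fold ones. That simulation held counting noise alone. Changes in rarer genes were not simulated.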

Other observations

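Several genes of dense-core vesicles, which store neuropeptides, are in none of the fixed lists, and as a group they were not tested. The genes in this paragraph and the next were chosen after their values were seen. Cpe, which trims peptide precursors, had 2298 ± 426 CPM (SD, n = 2), and Pcsk1n, an inhibitor of the convertase PC1, had 1743 ± 1144 CPM. Pcsk1n was lower in replicate 2 (log2 ratio -1.45), as was Vgf (13.8 ± 11.9 CPM, log2 ratio -1.97), both past the limits of the exact binomial test. The granins Chgb (383 ± 1.56 CPM), Scg2 (259 ± 17.7 CPM), Chga (226 ± 99.9 CPM) and Scg3 (208 ± 11.1 CPM), the chaperone gene Scg5 (445 ± 72.6 CPM) and the convertase gene Pcsk2 (188 ± 8.36 CPM) did not pass both limits.

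Tubulin genes followed with Tuba1a at 3223 ± 183 CPM (SD, n = 2), Tubb2a at 1632 ± 387 CPM and Tuba1b at 1562 ± 67.9 CPM, and the neuronal Tubb3 had 601 ± 112 CPM. Among long non-coding RNAs, the nuclear Malat1 had 201 ± 47.4 CPM and the imprinted Meg3 had 62.1 ± 6.42 CPM.

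For the genes that differ between the replicates, all tests were chosen after the differing genes and their GC content had been seen, and the test of read length was put in its final form after an earlier form of it, but the limits for isoform pairs and overlapping genes were written before the results of those tests. Lower yield of GC-rich sequence in replicate 2 may be involved: in 192 of 316 genes with a pair of known isoforms, called or not, the GC-richer isoform had the lower ratio (60.8%, 95% interval 55.1 to 66.2). Synaptic vesicle and immediate early genes both kept an adjusted p of 0.00230 among random lists matched on peak GC content. This argues against peak GC content as the whole cause in these 2 lists, as far as the few bins of peak GC content matched it. The random lists were not matched on the GC content of the whole transcript, so GC content in that form stays open as the whole cause. Its rho with the log2 ratio was -0.27, against -0.25 for the peak. A difference between the tissue pieces was not tested. Shorter reads from degraded RNA or from early stops of the reverse transcriptase stay open too, since the share of reads lacking the 5' end in the genes lower in replicate 2 was 16.5 percentage points above that of the same genes in replicate 1 (bootstrap interval 13.5 to 19.6), against 1.79 points in genes not called. Different assignment of reads between overlapping genes is argued against for the genes lower in replicate 2, where 3.73% (2.41 to 5.50) came within 2-fold by place, and for the genes higher it is kept open for some by a share of 9.95% (6.10 to 15.1), whose interval spans the limit of 10%.

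For antisense reads that mirror sense reads, both tests were chosen after the result was seen. In unspliced reads of spliced genes the antisense share was 27.8% in replicate 1 and 27.9% in replicate 2, against 6.62% and 9.87% in single-exon genes and 1.99% and 5.43% in mitochondrial genes. Loss of orientation in all unspliced reads alike is argued against by the lowest ratio of these shares, 2.83. Transcripts of their own could not be separated from mirrored reads over all antisense reads. Of single-exon antisense reads, 33.9% in replicate 1 and 27.6% in replicate 2 had a sense model with both ends within 50 bases. These shares lay between the limits set for either outcome. After a shift of the positions by 2000 bases they were 0.0526% and 0.0291%. Matching ends were thus far more frequent than at shifted positions, but most of these antisense reads had no such partner.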
